A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

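Total RNA from 4 yeast samples was measured on 4 Affymetrix arrays whose probe sets cover both *S. cerevisiae* and *Schizosaccharomyces pombe*. Per the labels' protocols, 50 ng of RNA was amplified with a whole-transcriptome kit and labelled with biotin before hybridization. No array repeats a sample, so variation from amplification could not be measured. The values used are the log2 signals per probe set that the authors deposited. Per the submitters' processing notes they came from GCRMA, a method that subtracts a background estimated from probe sequence and normalizes arrays to a common distribution; its version and settings are not given in the sources used here. The deposited log2 values ran from 1.50 to 15.10. GCRMA pulls absent transcripts to a narrow band at the bottom, which stretches folds that start or end there.

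The table held 10928 probe sets. Through a table of probe set annotation, 5498 named 1 *S. cerevisiae* gene, 1746 were annotated to *S. pombe*, 1 named several genes and 3683 had no gene name here, of which 213 were control or reporter probe sets. Symbols were updated by gene identifier to those of the RefSeq gene table for 12 probe sets. Probe sets of the same gene were averaged, which gave 5449 genes, 47 of them with more than 1 probe set. Since no *S. pombe* RNA was in the samples, the 95th percentile of its probe sets over all arrays, 2.31, served as the floor, and a gene entered a comparison when its brighter array lay above it. The *S. pombe* medians per array were 2.16, 2.18, 2.18 and 2.19 for untreated wild type, treated wild type, untreated sod1Δ and treated sod1Δ. Where the dimmer array was at or under the floor, a fold is given as at least the brighter level over the floor. It is a bound on the deposited signal and not on the transcript. Arrays give no counting depth.

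Samples were grouped by the labels into wild type and sod1Δ, each untreated or treated with H2O2. The 4 pairwise comparisons were treated over untreated in each strain and sod1Δ over wild type in each condition. With 1 array per group these comparisons leave no residual degrees of freedom, so there is no test of them and genes were counted past a 2-fold difference. A fit of shared strain and treatment effects over all 4 arrays, which would take the responses as equal in both strains, was not run. Attenuation meant a gene induced at least 2-fold in 1 strain whose fold in the other strain was under 50% of it, and the count with the strains exchanged was the background for it. The 8 pairwise counts share arrays, as do attenuation and the untreated difference, since each uses both untreated arrays.

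For 32 gene lists written before the data were examined, the median log2 difference was set against 10000 random lists with the same number of genes in each of 20 level bins. The percentile describes these arrays and is not a test between conditions. Lists share members, for example *HSP26* in general stress and heat shock, and a name pattern placed the RNase P gene *RPP1* among the ribosomal proteins. In all, 160 list medians were computed, of which 78 lay outside the central 95% of random lists. Lists of unrelated genes would put 8 there. Genes of a list can move together and the comparisons share arrays, so 8 is not the number that chance would give for these lists. A further 5 lists were added after the data had been seen and are used in the closing section alone.

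The rule for named genes, also written before the data were examined, took the 10 largest increases and 10 largest decreases of each pairwise comparison past 2-fold and the floor, the 15 largest drops among attenuated genes in each direction, and up to 4 members of each list with the largest change in each comparison. It always took the *SOD1* neighbourhood, stress regulators, mating type genes and auxotrophic markers. All members are named where a list had few attenuated genes. The text names a selection of these, and the genes of the 5 added lists were picked after their values were seen.

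The precision was judged from 42 genes whose 2 probe sets could be compared, from 18 hybridization control probe sets, from the 3′ minus 5′ difference of 7 control genes, and from a simulation in which both strains had equal responses and an assumed noise. Its median SD of 0.189 per array came from the spread of the response difference over genes of like level, not from repeated arrays. The steps were tested on simulated data with 5449 genes and a noise SD of 0.2 per array. Planted genes had a wild type response of at least 2.5 and lay above 6 on at least 1 array. Noise was the same at all levels, and the untreated strains had equal levels before noise. The recovery therefore does not cover genes induced less, dim genes or a raised untreated level. Of 100 genes planted with a drop of 1.5 in their induction in sod1Δ, 92 were recovered, and of 100 planted with a drop of 2.5 all 100; 7 unplanted genes were called, and 10 with the strains exchanged. Of 100 random gene lists 5 lay outside the central 95%, and all 100 shifted lists lay above it.

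The alternatives were thresholds of 1.5-fold and 3-fold, no floor, a floor raised by 1, centring each array on its median, quantile normalization over *S. cerevisiae* probe sets, the brightest probe set of each gene, adding 32 to the linear signal before log2, and 3 other definitions of attenuation. A floor of 6 and a selection of induced genes on the mean of both strains were added after the data had been seen. The analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genomic positions are not given because no genome build was used here.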

Results

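Transcript levels were measured on Affymetrix yeast arrays in haploid *Saccharomyces cerevisiae* of a strain named FM391 in the labels. Wild type cells were set against cells lacking *SOD1*, the gene of the cytosolic copper-zinc superoxide dismutase that turns superoxide into hydrogen peroxide. Each strain was measured untreated and after 20 min in 0.4 mM H2O2, in early log phase (OD600 about 0.4) at 30 °C in synthetic medium without leucine. There was 1 array per strain and condition, 4 in all, so nothing below has a replicate check, and each difference compares arrays, not populations of cultures. A gene was called higher or lower when its level differed at least 2-fold, and no p-value is given. Levels are log2 signals, and 5449 genes were measured, of which 5335 lay above the background floor of 2.31 in untreated wild type, 5330 in treated wild type, 5312 in untreated sod1Δ and 5313 in treated sod1Δ.

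The *SOD1* transcript followed the labels. It was at 14.21 and 14.31 in untreated and treated wild type, and at 2.40 and 2.42 in sod1Δ, close to background. The neighbouring genes *URA8* and *ADO1*, and *CCS1*, which encodes the copper chaperone for Sod1, differed by 0.17, -0.16 and -0.04 between the untreated strains. *CCS1* went from 10.98 to 12.35 with H2O2 in wild type and from 10.94 to 12.14 in sod1Δ. Transcripts of the a mating type were abundant in all samples, with *MFA1* between 11.60 and 12.30, while *MF(ALPHA)1* stayed between 2.18 and 2.22. The other alpha markers were above the floor, with *MF(ALPHA)2* at 7.40 to 8.88, *SAG1* at 8.11 to 8.83 and *STE3* at 6.72 to 8.62. *LEU2* was the brightest of the auxotrophic markers at 14.27 to 14.76, from the chromosome or a plasmid, which cannot be told here, and *URA3* and *MET17* were at background on all 4 arrays.

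**Figure D1:**
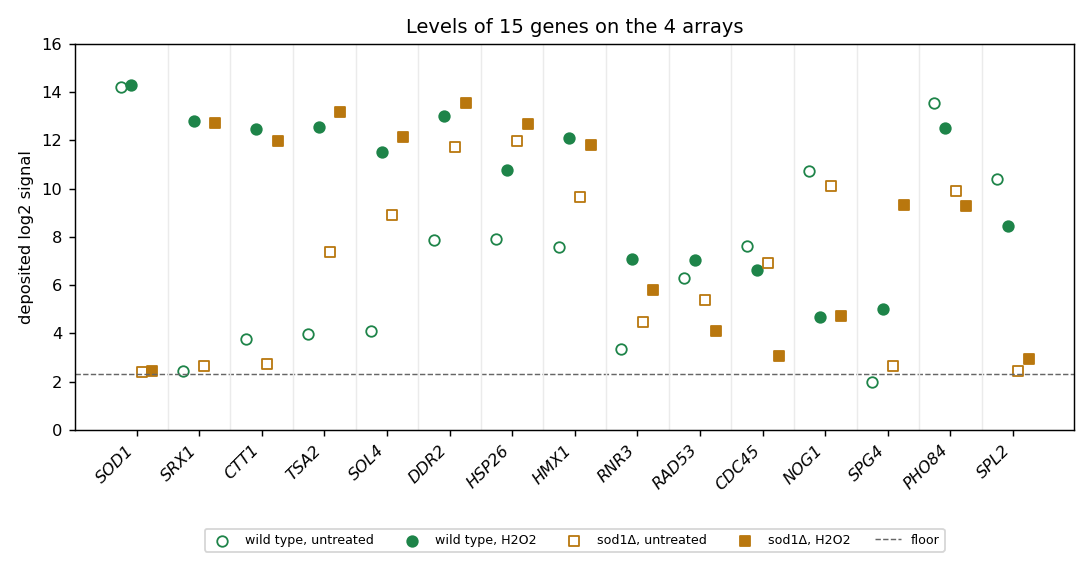
Deposited log2 signal (vertical axis) of 15 genes on the 4 arrays, with circles for wild type, squares for sod1Δ, open symbols for untreated and filled symbols for H2O2-treated samples; the dashed line is the floor of 2.31. *SOD1* is at 14.21 and 14.31 in wild type and at 2.40 and 2.42 in sod1Δ, while *SOL4*, *DDR2* and *HSP26* are higher in untreated sod1Δ than in untreated wild type.

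The first comparison asked which genes respond to H2O2 in wild type. Genes of peroxide removal and detoxification led the increases. *SRX1*, encoding the sulfiredoxin that repairs over-oxidised peroxiredoxins, was at 2.42 untreated and 12.81 after H2O2. The catalase gene *CTT1* was at 3.78 and 12.46, the peroxiredoxin gene *TSA2* at 3.97 and 12.55, and the glutathione transferase gene *GTT2* at 3.61 and 11.90. Among the genes of glutathione, thioredoxin and peroxide defence, 17 of 32 were higher and 0 lower, with a median change of 1.23. Genes linked to the peroxide-activated transcription factor Yap1 were higher in 15 of 20 cases, with a median of 3.12. They included *AAD6* (8.41), the old yellow enzyme gene *OYE3* (8.22), *FRM2* (7.87) and the transcription factor gene *CIN5* (7.71). *YHK8*, a presumed transporter gene, was higher by 7.39 and *YAP1* itself by 1.66. In all, 915 genes were higher and 862 lower of the 5358 above the floor on at least 1 of these arrays.

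Stress and reserve genes were higher along with them. Of the targets of the general stress factors Msn2 and Msn4, 25 of 28 were higher (median 2.42), led by *SOL4* (4.11 untreated and 11.50 after H2O2), *RTN2* (5.47) and *DDR2* (5.13). Trehalose and glycogen genes were higher in 14 of 17 cases and lower in 1 (median 2.08), with the glycogenin gene *GLG1* at 3.97 and the trehalose phosphatase gene *TPS2* at 3.06. Genes of autophagy and vacuolar proteases were higher in 12 of 17 (median 2.26), including *ATG29* (3.71) and the kinase gene *ATG1* (2.88). Post-diauxic and gluconeogenic genes were higher in 10 of 18 and lower in 1 (median 1.11), with the malate synthase gene *MLS1* at 3.27. The pentose phosphate list had 6 of 13 genes higher and 1 lower (median 0.87), and iron genes had 12 of 30 higher (median 0.52), with the heme oxygenase gene *HMX1* at 4.49. Sulfur amino acid genes went both ways, with 8 of 28 higher and 5 lower (median 0.42), and *MET28*, a regulator of that pathway, at 2.76. The stress regulators were higher in 4 of 15 cases (median 0.76), among them *RPN4* (1.61) and *DUN1* (1.09).

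Genes of ribosome biogenesis and of the cell cycle were among the largest decreases. All 39 genes of ribosome biogenesis were lower, with a median of -3.44. *RRS1* of that list was at 9.93 untreated and 3.42 after H2O2. Outside the list, the ribosome assembly genes *NOG1* and *RSA4* were at 10.73 and 4.67 and at 8.68 and 2.08. The last was at background, so *RSA4* was at least 82.5-fold lower in deposited signal, which stretches folds that end there. *TOD6*, a repressor of ribosome biogenesis genes, was itself at 8.92 and 2.89. Ribosomal protein genes were lower in 18 of 128 cases with a median of -0.56, for example *RPS9A* (-2.08). Cell cycle genes were lower in 6 of 16 for G1 and S phase (median -0.81) and in 6 of 15 for mitosis and early G1 (median -0.86). The G1 cyclin gene *PCL1* was at 8.55 and 2.33, *CLN2* was lower by -2.44 on the log2 scale and the mitotic cyclin gene *CLB2* by -2.59. Core histone genes were lower in 4 of 7 (median -1.07), and ergosterol genes in 7 of 24 (median -0.54), with *ERG3* at -1.71.

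The medians of 18 of the 32 gene lists lay outside the central 95% of random lists matched on level, where lists of unrelated genes would put 1.6. All list medians of this comparison named in the 3 paragraphs above are among the 18, as are those of arginine and histidine synthesis (0.45, 5 of 13 higher and 1 lower) and branched-chain amino acid synthesis (0.25, 0 of 10 past 2-fold). DNA damage genes were inside with a median of 0.35, although *RNR3*, encoding a damage-induced ribonucleotide reductase subunit, was higher by 3.74 and the DNA glycosylase gene *OGG1* lower at -2.53. Heat shock chaperones were inside too (median -0.08), with 7 of 24 higher and 3 lower. The other medians inside were 0.01 for the proteasome, 0.28 for copper, -0.38 for zinc, 0.02 for lysine synthesis, -0.22 for glycolysis, 0.24 for respiration, -0.26 for the unfolded protein response, -0.54 for a mating type and 0.86 for alpha mating type genes, 0.42 for auxotrophic markers and 0.31 for the *SOD1* neighbourhood. The cell wall median, -0.03, was above 0 after quantile normalization and after centring on the array median. Of 42 genes with 2 probe sets, the probe sets of 8 differed at least 2-fold in this change, which gives an SD of 0.51 per probe set. The 18 hybridization control probe sets differed by a median of -0.44 between these arrays, with a range from -1.40 to 0.01, so some passed the 2-fold threshold. Their median was 0.11 for the response in sod1Δ, -0.22 between the untreated strains and 0.28 between the treated strains.

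The second comparison asked which genes respond in sod1Δ. Of the 10 largest increases 6 were shared with wild type. *SRX1* was at 2.66 untreated and 12.70 after H2O2, *CTT1* at 2.74 and 11.98, *AAD6* at 2.40 and 11.95, and *OYE3* at 5.20 and 13.49. Peroxide defence genes were higher in 16 of 32 cases and lower in 1 (median 1.02), and Yap1-linked genes in 15 of 20 (median 2.44). Ribosome biogenesis genes were lower in 38 of 39 cases (median -3.41), and ribosomal protein genes in 28 of 128 (median -0.61). *DRS1*, a helicase gene of ribosome assembly outside that list, was at 11.01 untreated and 3.94 after H2O2. In total 782 genes were higher and 844 lower of 5341, and 826 higher and 787 lower after quantile normalization. The sets shared 665 higher genes, where independent sets of these sizes would share 133, and 674 lower genes, against 136.

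Several groups had other values in this strain. General stress targets were higher in 20 of 28 (median 1.83), trehalose and glycogen genes in 12 of 17 (median 1.13), and autophagy genes in 11 of 17. G1 and S phase genes were lower in 13 of 16 (median -1.97), with *CDC45*, whose product is part of the replicative helicase, at 6.92 and 3.07. Heat shock chaperones were higher in 7 of 24 and lower in 0 (median 0.57), led by *CUR1* (4.66), *HSP42* (3.07) and *BTN2* (2.65). Post-diauxic genes were higher in 11 of 18 and lower in 1 (median 1.33), the pentose phosphate list in 5 of 13 with 1 lower (median 0.77), and respiratory genes in 6 of 28 (median 0.37), with the cytochrome c gene *CYC1* at 3.94. *SPG4*, a gene of stationary phase survival, was at 2.66 and 9.32. Mitosis genes (median -0.62, 5 of 15 lower) and ergosterol genes (median -0.49, 4 of 24 lower) completed the 14 lists outside the central 95% of random lists. Medians inside it included 0.12 for iron, 0.24 for sulfur, -0.45 for histones, 0.02 for DNA damage, 0.14 for stress regulators, 0.10 for the proteasome and 0.16 for arginine and histidine synthesis. Across 5365 genes the responses of the strains correlated with r = 0.924 (Spearman rho = 0.913), from separate pairs of arrays, although genes are not independent replicates.

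**Figure D2:**
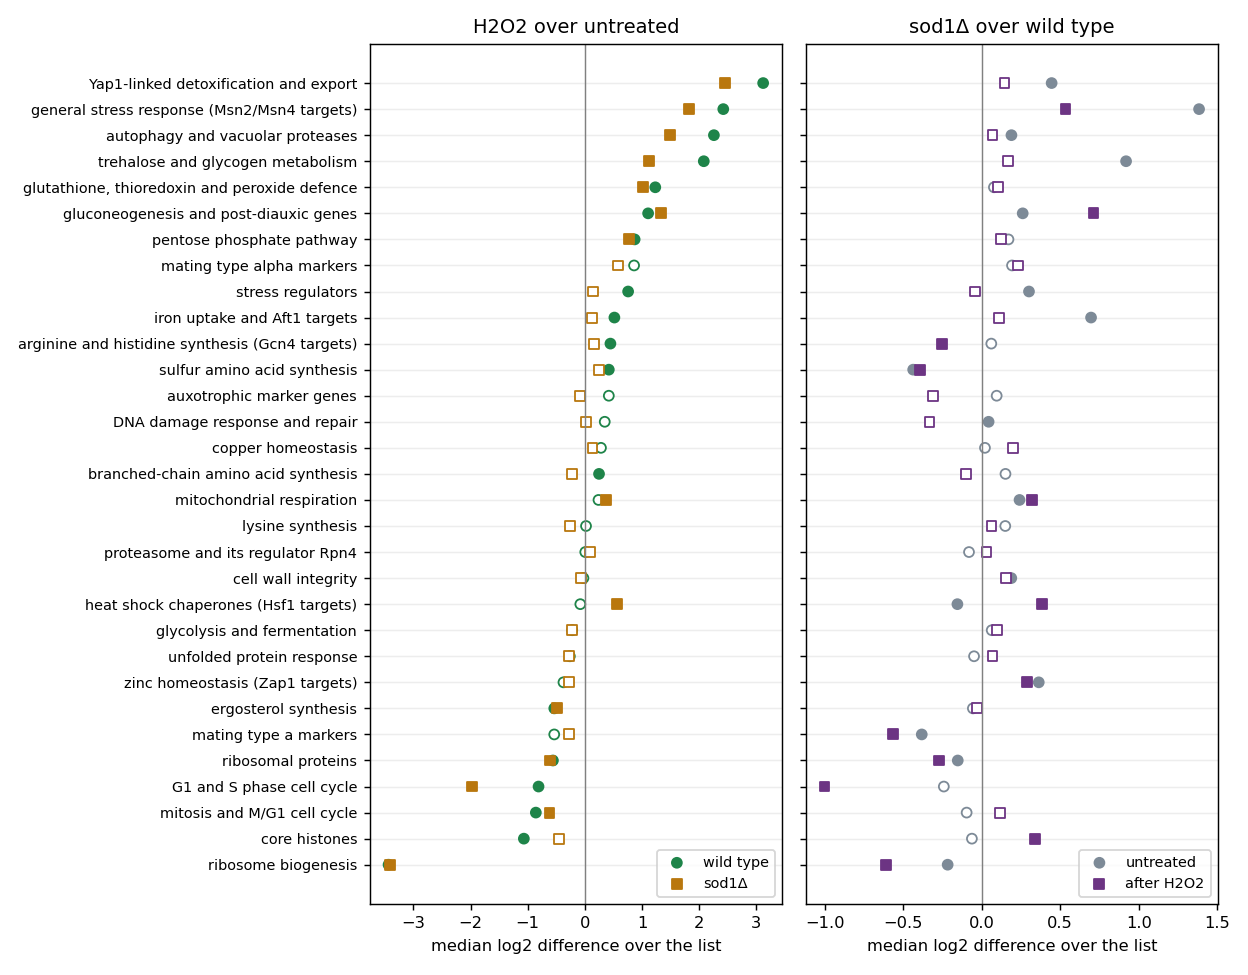
Median log2 difference over each gene list fixed in advance (31 of 32 lists drawn, without the *SOD1* neighbourhood), on the left after H2O2 over untreated in each strain and on the right sod1Δ over wild type in each condition; filled symbols lie outside the central 95% of level-matched random lists. Ribosome biogenesis is lowest on the left at -3.44 and -3.41, and the general stress list is highest on the right at 1.38 for untreated samples.

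The third comparison asked how the untreated strains differed. Msn2 and Msn4 targets were higher in sod1Δ in 19 of 28 cases and lower in 0, with a median of 1.38. *SOL4* was at 4.11 in wild type and 8.92 in sod1Δ, the small heat shock protein gene *HSP26* at 7.90 and 11.98, and *DDR2* at 7.86 and 11.75. *TMA10*, outside that list, was at 2.88 and 7.98. Trehalose and glycogen genes were higher in 7 of 17 (median 0.92), such as the debranching enzyme gene *GDB1* (2.34), and Yap1-linked genes in 6 of 20 (median 0.44), such as *HBN1* (3.23). Iron genes were higher in 10 of 30 and lower in 1 (median 0.70), with the cell wall iron-binding protein gene *FIT1* at 5.92 and 10.21. *TSA2* was higher by 3.41, but the peroxide defence list as a whole had a median of 0.08, inside the random range, with 3 genes higher and 1 lower. Of 5344 genes, 198 were higher and 170 lower.

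After *SOD1* itself, the 4 largest decreases were phosphate genes. *SPL2* was at 10.41 in wild type and 2.45 in sod1Δ, *PHO11* at 11.88 and 5.55 on a probe set that other transcripts can share, *PHO89* at 8.56 and 3.21, and the acid phosphatase gene *PHO5* at 12.23 and 7.93. The high-affinity transporter gene *PHO84* was at 13.54 and 9.93. Sulfur amino acid genes were lower in 9 of 28 and higher in 0 (median -0.44), including *MET14* (-1.96) and *MET3* (-1.41). *ANB1*, a gene repressed by oxygen, was at 7.21 and 3.04. Ribosomal protein genes had a median of -0.15 and ribosome biogenesis genes of -0.22, with 1 of 128 and 0 of 39 lower.

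Of the 32 list medians 16 lay outside the central 95% of random lists. Besides those above, they were heat shock (-0.15), DNA damage (0.04, at the edge of the random range and inside it after quantile normalization, with the brightest probe set and with 32 added), zinc (0.36), respiration (0.24), post-diauxic genes (0.26, and 0.14 with 32 added), cell wall (0.19), a mating type (-0.38), autophagy (0.19, with 0.31 after quantile normalization and 0.11 with 32 added) and stress regulators (0.30). In the DNA damage list *HUG1*, induced by replication stress, differed by 3.17. Probe set pairs gave an SD of 0.31 per probe set for this difference, and quantile normalization over *S. cerevisiae* probe sets gave 229 genes higher and 129 lower. Adding 32 to the linear signal, which damps dim genes, gave 147 higher and 71 lower.

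The fourth comparison asked how the strains differed after H2O2. G1 and S phase genes were lower in sod1Δ in 8 of 16 cases and higher in 0 (median -1.0004), with *CDC45* at 6.61 in wild type and 3.07 in sod1Δ, *CLB6* at 5.31 and 2.35, and the cohesin gene *MCD1* differing by -2.18. The DNA damage list had 5 of 29 genes lower and 1 higher, with a median of -0.33 inside the random range (-0.15 after quantile normalization). Among its lower members, *RAD53*, encoding the DNA damage checkpoint kinase, was at 7.05 and 4.09, *DUN1*, encoding the kinase that acts downstream of it, at 9.94 and 8.45, and *OGG1* at 4.82 and 2.42. The centromeric histone gene *CSE4* was at 6.02 and 2.51 and the spindle pole gene *SPC29* at 6.58 and 2.68. Ribosome biogenesis genes were lower in 10 of 39 and higher in 3 (median -0.61), from *MAK21* at -2.74 to *NSR1* at 2.21.

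Genes of several kinds were higher in treated sod1Δ. Post-diauxic genes were higher in 7 of 18 and lower in 0 (median 0.71), including *CAT8* (2.31) and *ADH2* (1.26). The transketolase gene *TKL2* was at 7.97 in wild type and 11.17 in sod1Δ, *SPG4* at 5.01 and 9.32, *PDC5* at 7.15 and 9.97, and the thiamine gene *THI4* at 8.62 and 12.49. General stress targets had a median of 0.53, smaller than the 1.38 between the untreated strains. Of these targets 3 of 28 were higher, among them *MOH1* (2.62) and *HSP26* (1.92). Heat shock chaperones had a median of 0.39, with 3 of 24 higher. The phosphate genes *SPL2* and *PHO84* were lower here too, at 8.47 and 2.96 and at 12.52 and 9.27. The other lists outside the random range were ribosomal proteins (-0.27), sulfur amino acids (-0.39), arginine and histidine (-0.25), zinc (0.29), respiration (0.32), histones (0.34) and a mating type (-0.57), which makes 12 of 32.

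In all, 164 genes were higher and 338 lower of 5341 after H2O2. Quantile normalization turned that split into 230 higher and 215 lower, and dim genes weighed heavily in it, since 126 of the 338 had a mean level under 6 and 118 a mean level between 6 and 8. Dim genes leaned the same way between the untreated strains, with 69 lower and 18 higher under 6, and 64 and 38 between 6 and 8. Over 10 the lean was opposite, with 6 lower and 86 higher untreated, and 14 and 27 after H2O2. The strains shared direction across conditions for 72 higher genes, where independent sets would share 6.05, and for 74 lower genes, against 10.7.

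The fifth comparison follows the design text, which looks for H2O2-induced genes that lost more than 50% of their induction without *SOD1*. Of the 915 genes induced in wild type, 100 (10.9%) had a fold induction in sod1Δ below 50% of that in wild type. General stress genes were prominent, with 11 of the 25 induced targets of Msn2 and Msn4 attenuated: *ALD3*, *DDR2*, *GAD1*, *HSP12*, *HSP26*, *MSC1*, *PGM2*, *RTC3*, *RTN2*, *SOL4* and *SPI1*. *DDR2* was higher after H2O2 by 5.13 in wild type and 1.82 in sod1Δ, and *HSP26* by 2.88 and 0.72. All 11 were already at least 2-fold higher in untreated sod1Δ. None of the 11 was lower in sod1Δ after H2O2, with treated differences from 0.03 (*GAD1*) to 1.92 (*HSP26*). The same held for the attenuated Yap1-linked genes and for *TSA2*, so their smaller folds went with higher untreated levels. Yap1-linked genes were attenuated in 5 of 15 cases, iron genes in 3 of 12, with *HMX1* at 4.49 and 2.14, and trehalose and glycogen genes in 3 of 14. Peroxide defence genes were attenuated in 1 of 17 cases, *TSA2*, at 8.58 and 5.80.

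Higher untreated levels and lower treated levels both occurred among the attenuated genes. For 50 of the 100 the untreated level was at least 2-fold higher in sod1Δ, and for 42 of these the treated level in sod1Δ was not reduced, while for 8 it was lower than in wild type. *HSP30* was among the 42, at 5.91 and 13.06 in wild type and 9.06 and 13.57 in sod1Δ, as were *RGI1* and *YML131W*. For 35 genes the treated level was at least 2-fold lower in sod1Δ. Among them were *PLM2* (7.75 against 5.04), *DUN1* (9.94 against 8.45) and the autophagy gene *ATG16* (5.66 against 2.27, the latter under the floor). *RNR3* met both conditions, and 16 genes met neither. The 35 held all 13 attenuated genes that were below 6 on all arrays, so dim genes weighed in this group. Of the 100 genes, 60 were still higher by at least 2-fold in sod1Δ and 7 were not higher at all.

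**Figure D3:**
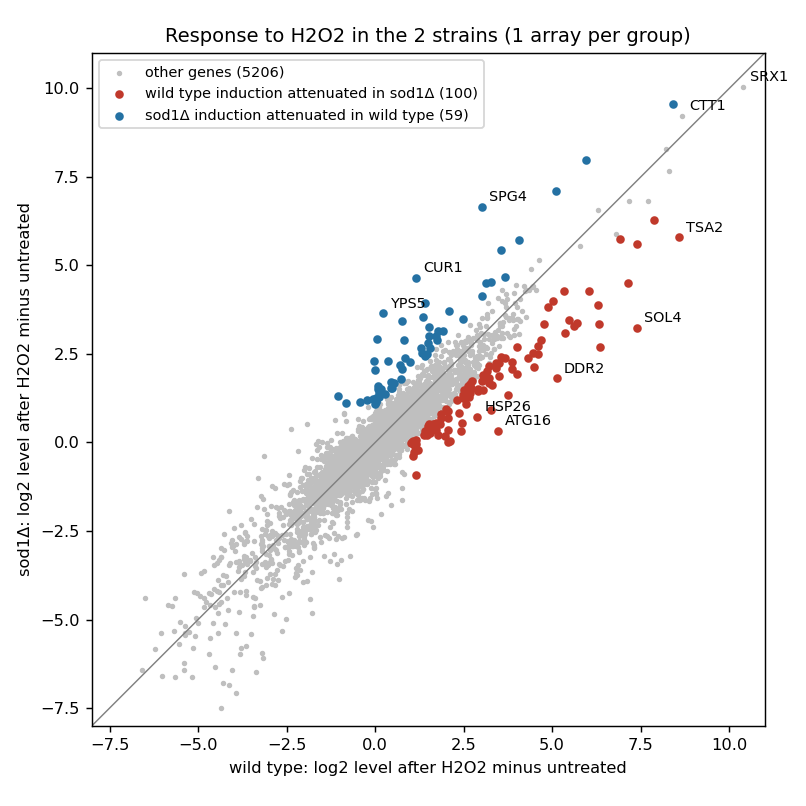
Log2 change after H2O2 in wild type (horizontal axis) and in sod1Δ (vertical axis) for each gene above the floor on at least 1 array; the grey line marks equal change. Red points are the 100 genes whose wild type induction was attenuated in sod1Δ, and blue points the 59 genes with the strains exchanged.

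With the strains exchanged, 59 (7.54%) of the 782 genes induced in sod1Δ had a fold induction in wild type below 50% of that in sod1Δ. *SPG4* was under the floor in untreated wild type and at 5.01 after H2O2, against 2.66 and 9.32 in sod1Δ. *CUR1*, encoding a sorting factor for misfolded proteins, was higher by 1.14 in wild type and 4.66 in sod1Δ, and *TKL2* by 1.41 and 3.93. *YPS5* and *HXT10* were at 2.49 and 2.41 in treated wild type, close to background, and at 5.95 and 5.89 in treated sod1Δ. The post-diauxic list contributed *ADY2*, *CAT8* and *MLS1*, and the general stress list 0 of its 20 induced genes. The list medians of response in sod1Δ minus response in wild type were -0.74 for general stress, -0.58 for trehalose and glycogen, -0.54 for iron, -0.45 for Yap1-linked genes and -0.71 for G1 and S phase, and 0.59 for heat shock chaperones, 0.52 for histones and 0.27 for post-diauxic genes, all outside the random range. For peroxide defence it was -0.03, inside it. In this comparison 18 of the 32 list medians lay outside the random range. DNA damage was among them, at -0.29 against a random range of -0.24 to 0.14, and at -0.30 after quantile normalization, also outside. The random lists were matched on level and not on induction. Over the 838 genes induced at least 2-fold on the mean of both strains, the median response difference was -0.22, and 65.6% responded less in sod1Δ. A list rich in induced genes can therefore lie below the random range without differing from other induced genes.

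The excess of attenuated genes over the exchanged count depends on the definition: asking instead for a treated level under 50% of that in the other strain gave 69 genes in sod1Δ and 74 in wild type. Noise alone would give attenuated genes in both directions, but noise between cultures or arrays was not measured. For the response difference, the 42 genes with 2 probe sets gave an SD of 0.45 per probe set. The probe sets of 3 of them differed at least 2-fold. In 100 simulations with equal responses in both strains and an assumed noise, 31.6 genes on average were attenuated in sod1Δ (range 19 to 44) and 30.45 in wild type (range 16 to 46). That noise was taken from the spread of the response difference over genes and not from repeated cultures or arrays, so the count that chance would give is not known.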

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

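No test was run on the differences in this part, since each group had 1 array, and the choice of what to list follows from opposite signs in the 2 strains or from signal in probe sets without a gene name. Only *TIR1*, a cell wall mannoprotein gene, was at least 2-fold lower after H2O2 in wild type and at least 2-fold higher in sod1Δ. Its change was -1.06 in wild type and 1.31 in sod1Δ, and its untreated level was 8.81 in wild type and 5.68 in sod1Δ. The difference was not tested.

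The median response had opposite signs in the strains for 4 of the 32 gene lists fixed in advance, and these differences were not tested either. Heat shock chaperones had -0.0803 in wild type and 0.57 in sod1Δ, of which the sod1Δ value alone lay outside the central 95% of random lists. Lysine synthesis had 0.0193 and -0.26, both inside that range. Branched-chain amino acid synthesis had 0.25, outside, and -0.22, inside. Auxotrophic marker genes had 0.42 and -0.0929, both inside. The signs were the same after centring, after quantile normalization, with the brightest probe set and with 32 added.

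Probe sets without a gene name here, 3470 after leaving out controls and reporters, also responded. In wild type 72 of them were at least 2-fold higher after H2O2 and 22 lower, and in sod1Δ 67 were higher and 23 lower, while 0 of the 1746 *S. pombe* probe sets changed that much in either strain. Of these unnamed probe sets 195 were above 6 on at least 1 array.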

How the results depend on the processing

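Leaving out each replicate in turn was not possible with 1 array per group. No paired analysis was possible because each group holds 1 array, so the pairwise results come from no test. Among the list medians outside the random range and the named changes compared, 0 changed sign under other processing. Which direction held more genes did turn, in wild type and between untreated strains at 1.5-fold and, under quantile normalization, for the response in sod1Δ and between treated strains. A floor raised by 1, no floor, the brightest probe set and centring on the array median kept all 11 counts within 1.5 times, as did the floor of 6 for 10 counts and, for attenuation, the log2 definition, the treated-level definition and selection on the mean of both strains (81 and 42 genes), the floor of 6 and the last of these chosen after seeing the data. The treated-level definition gave 69 genes attenuated in sod1Δ and 74 in wild type, so the excess of 100 over 59 turned the other way, and the log2 definition gave 109 and 60. They do not pick the same genes: 35 of the 69 and 50 of the 109 were among the main 100.

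The larger moves were these, and where the threshold itself did not set them the cause was not tested. At 1.5-fold, 1386 genes were higher and 1405 lower in wild type, 1266 and 1349 in sod1Δ, 460 and 543 between untreated strains, and 482 and 806 after H2O2. At 3-fold the counts were 492 and 479, 424 and 463, 78 and 39, and 62 and 123. With 32 added to the linear signal, which damps dim genes, 71 genes were lower in untreated sod1Δ, 155 lower in treated sod1Δ, 60 attenuated in sod1Δ and 26 attenuated in wild type. Quantile normalization left 215 genes lower in treated sod1Δ, 212 of them among the 338. By linear increment, 144 genes were attenuated in sod1Δ and 118 in wild type, so the 2 directions differ less there. List medians outside the random range numbered 78 of 160 as deposited and 74 to 78 under the other settings. Of 457 named gene changes, 183 moved by more than the probe set SD when 32 was added and 16 under quantile normalization. Signal over background limits the dim genes: 13 of the 100 attenuated genes were below 6 on all arrays.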

Other observations

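All tests in this part were chosen after the results were seen, except the position of attenuated genes relative to the top of the signal range, and the 5 gene lists used here were also written after. Phosphate starvation genes were lower in untreated sod1Δ in 9 of 14 cases (median -1.80) and lower after H2O2 in 6 of 14 (median -0.97). In wild type H2O2 itself went with lower levels in 8 of 14 and higher in 2 (median -1.03), including *PHM6* (-3.80), while in sod1Δ it did so in 1 of 14 (median -0.32). Thiamine genes were higher in untreated sod1Δ in 7 of 12 (median 1.04), with *THI4* at 10.01 in wild type and 13.31 in sod1Δ. *THI13*, on a probe set that other transcripts can share, was at 8.39 and 12.09.

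Genes repressed by oxygen went both ways after H2O2, with 4 of 12 higher and 5 lower in each strain, but with medians of -0.44 in wild type and 0.34 in sod1Δ, both inside the random range, and a median difference between the responses of 0.32, above it. *CYC7* was higher by 6.29 in wild type and 6.57 in sod1Δ, and *AAC3* was at 8.77 and 5.53 in wild type and at 6.34 and 2.23 in sod1Δ, the last at background. DNA replication genes had medians of -0.40 in wild type, inside the random range, and -0.93 in sod1Δ, outside it, with 10 and 15 of 32 lower and 3 and 1 higher. The replication clamp gene *POL30* differed by -1.79 and -3.65. Kinetochore and spindle pole genes had a median of -0.60 between the untreated strains and -0.74 after H2O2, with 4 of 16 lower in each and 1 higher after H2O2. The latter median was -0.45 after quantile normalization, still below the random range of -0.35 to 0.38.

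The first pattern is that 50 of the 100 attenuated genes were already at least 2-fold higher in untreated sod1Δ. The rule for attenuation uses both untreated arrays, so a raised untreated level is partly built into the set. With the strains exchanged, 9 of the 59 genes were at least 2-fold higher in untreated wild type. For 31 of the 59 the treated level was at least 2-fold lower in wild type. Chance low readings on the untreated wild type array alone would leave no difference between the treated arrays, but over these genes the treated difference had a median of 0.48, above the random range of -0.14 to 0.12. A signal ceiling could limit the treated level but not raise the untreated one, so it stays open only as a limit on induction. In treated sod1Δ, 18 of the 50 lay above 12.75, the 95th percentile of that array, and the others below. That percentile is not a saturation level, since genes on that array reached 14.88, so the count does not decide the question. A different culture stage may also contribute: post-diauxic genes had a median of 0.26 in untreated sod1Δ, above the random range of -0.40 to 0.06 (0.14 with 32 added), and with 1 culture per group it cannot be told apart from the genotype. A stress programme running in sod1Δ before H2O2 is a hypothesis that remains open beside these.

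The second pattern is the excess of lower genes in treated sod1Δ, 338 against 164. The lean of dim genes is not particular to the treated arrays. Under a mean level of 6, 126 genes were lower and 38 higher after H2O2, and 69 lower and 18 higher untreated. Quantile normalization left 215 lower and 230 higher, but it forces the arrays to a common distribution. It would remove a real excess of lowered dim genes too, so whether the deposited normalization accounts for the excess was not decided. A difference in array scaling does not account for the G1 and S phase genes. Their median was -0.92 after quantile normalization, below the random range of -0.32 to 0.28. Quantile normalization cannot undo the stretching of folds that end near the bottom, as for *CDC45* at 3.07 in treated sod1Δ. The size of such differences therefore stays open. Poorer RNA was not decided: the 3′ minus 5′ difference was largest on that array for 3 of 7 control genes, where chance gives 1.75, but smallest for another 3, and its median there, 0.778, was the lowest of the 4 arrays (0.864, 0.991 and 0.999 on the others). A stronger arrest of DNA synthesis in sod1Δ is a hypothesis that these arrays cannot separate from a difference between cultures.

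The third pattern is the lower phosphate genes in sod1Δ. Chance high readings on the untreated wild type array would leave the treated arrays alike, but their median difference was -0.97, below the random range of -0.34 to 0.21. The phosphate list was written after the treated arrays had been seen too, so this is not an independent check. Distortion of low signals near background stays open for the size of some differences: 3 of the 9 lower genes, *SPL2*, *PHO89* and *PHO11*, were under 6 in untreated sod1Δ, where the 9 ran from 2.45 to 11.14. A difference in medium or culture may be the source and cannot be told apart from the genotype, since 6 of the 9 genes were lower in both conditions and each group had 1 array.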
